A study of Mus musculus with 12 samples.

How the data were processed

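RNA from 4 cell types of C57BL/10.RIII mice, labelled CD4+ or CD4hi, was measured on 12 Affymetrix Mouse430_2 arrays, 3 per cell type. Per the labels' protocols, total RNA was extracted with Trizol and treated with DNase, its quality and amount were read on a Bioanalyzer and a Nanodrop, and biotin-labelled cRNA was made by 3' one-cycle amplification. The submitters' processing notes name PLIER, a method that summarises the probes of a probe set. Its version, its role and any normalization between arrays are not given in the sources used here. Scanner files were not used here.

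The deposited table holds log2 probe set values for 45037 probe sets on 12 arrays, with no offset added, so that dim probe sets run far below 0. The log base was read from the values, whose maximum lies within the range of a scanner on a log2 scale. Affymetrix control probe sets were absent from the table (0 found), so the planned comparison of 5', middle and 3' control probe sets as a sign of RNA quality was not possible. Probe sets were named from the array annotation and matched to the reference gene table by Entrez identifier: 34945 had 1 gene, 932 had several, 9160 had none, and 34741 of those with 1 gene matched, with 0 symbols changed.

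Groups were taken from the labels. The comparisons, tests, gene lists, rule for named genes and alternatives, apart from 2 added later, were fixed before the data were examined. The array medians spanned 0.202 log2, above the tolerance of 0.2, so values were quantile normalized. Probe sets in the upper 60% by mean log2 over all arrays were kept (a level of 4.05), and each gene was represented by its brightest probe set with 1 gene symbol, which left 12609 genes. For 5649 genes with several kept probe sets, called probe sets of 1 gene pointed both ways for 65 genes in nFoxA1Treg against EncT, 40 in Treg against EncT, 0 in nFoxA1Treg against Treg, and 902, 937 and 946 where the arrays labelled iFoxA1Treg were compared with EncT, Treg and nFoxA1Treg. Of 266 called values of named genes, 111 had another probe set past the filter, and in 24 of these at least 1 such probe set was not called or pointed the other way. The widest of these gaps were in Tgfb1, Pdia4, Egr3, Foxp1, Lss and H2-Aa.

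Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 12 arrays (8 residual degrees of freedom), contrasts for the 6 pairs of groups, and eBayes with an intensity trend. P-values are two-sided and adjusted by Benjamini-Hochberg within each comparison, with an adjusted p under 0.05 as the threshold. The F test asks for a difference anywhere among the 4 groups. Errors beside group levels are standard deviations of normalized log2 values and SE is the standard error of a log2 change. Where a group mean lies near the floor, the largest rises and falls are also given on the scale log2(value + 16), while list members are given mostly on the normalized scale alone, where a change from near the floor depends on the noise there. On the former scale the value is 2 to the power of the deposited log2 value. Quantile normalization and the choice of the brightest probe set followed the offset, so the probe set of a gene can differ between the scales. The labels give replicate numbers and do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, and the replicates may be technical. Rises and falls are coded as the first-named group minus the second.

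The 29 gene lists covered the Foxp3 Treg core, inhibitory receptors and suppressive mediators, type I and gamma interferon responses, Th1, Th17 and Th2 effectors, T cell receptor and T lineage, immediate early genes, quiescence and homing, migration and adhesion, cell cycle, apoptosis, p53 targets, TGF-beta response, glycolysis, cholesterol synthesis, respiratory chain, unfolded protein and integrated stress response, heat shock, ribosomal proteins, and markers of neurons, astrocytes and oligodendrocytes, macrophages, dendritic cells with MHC class II, B cells, CD8 T and NK cells, neutrophils with mast and erythroid cells, and fibroblasts with endothelium. Some genes stand in 2 lists, and T cells also express part of the dendritic cell, CD8 T and NK lists. Lists were tested with camera (preset inter-gene correlation 0.01), which compares a list with all other genes, and adjusted over the lists of a comparison. Lists with under 5 measured members were not to be tested. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, and camera with an estimated correlation were alternatives. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

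Named genes were, in each comparison, 12 fixed genes (Foxa1, Foxp3, Cd274, Cd4, Cd47, Tgfb1, Pdcd1, Il10, Ifng, Il17a, Il2ra and Ctla4), the 5 largest rises and 5 largest falls among called genes without overlap between groups, and the 3 members with the smallest adjusted p of each called list. Not all of the latter are printed. The largest rises and falls were ranked with predicted genes of clone-type names (such as Gm with digits or Rik) left out. Fixed genes below the filter are given from a fit without it. Outside this rule, and chosen after their values were seen, stand members that moved against their list, Ikzf2, the genes Cd3e, Lyz2, Cd79b, Xist, Eif2s3y and Usp18 where they describe the arrays or stand in a figure, and the genes named for single alternatives. Genes named only in the closing section were also chosen after their values were seen.

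Alternatives were values as deposited, arrays centred on their medians, no filter and a filter at the upper 40%, the mean of all probe sets, the most variable probe set, every probe set tested, eBayes without trend and with a robust trend, array weights, only the arrays of the 2 groups, the replicate number as a block, each array left out in turn, and the 2 list tests. The scale log2(value + 16) and a fit without the arrays labelled iFoxA1Treg, with normalization and filter redone, were added after seeing the data. Whether Ttr reached the filter without each array was also checked only then. Power was tested on data simulated from the spread of these arrays, with 5 simulations of 200 changed genes, and chance overlap between comparisons that share a control with 100 simulations of unchanged groups. The 3 EncT arrays are too few to be split between the comparisons that share them. Figures were drawn with matplotlib 3.10.9.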

Results

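Whole-genome expression was measured on 12 Affymetrix Mouse430_2 arrays of cells labelled CD4+ or CD4hi, from C57BL/10.RIII mice, a strain used for experimental autoimmune encephalomyelitis, the mouse model of multiple sclerosis. The 4 cell types had 3 arrays each. Encephalitogenic T cells (EncT), the T cells that drive the disease, carried the surface label CD4+. Regulatory T cells (Treg) were labelled CD4+ and TGF-beta+. The remaining 2 groups were regulatory T cells named for the transcription factor FoxA1, both labelled CD4hi and PD-L1hi. One is called neuron induced in its titles and natural in its cell type field (nFoxA1Treg), and the other was induced with interferon beta (iFoxA1Treg). Array medians of the deposited log2 values ran from 4.64 to 4.84, and 3.85% to 5.65% of probe sets lay below 0. The number of arrays, 3 per group, limits the precision of every comparison.

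The 3 arrays labelled iFoxA1Treg stood apart from the other 9. Over all probe sets their Pearson correlation with other arrays was 0.683 to 0.739, against 0.815 to 0.847 between arrays of EncT, nFoxA1Treg and Treg. Within groups it was 0.828 to 0.857, across probe sets, which are not independent replicates. The upper end came from the arrays labelled iFoxA1Treg (0.846 to 0.857). EncT replicate 1 had a mean correlation of 0.836 with its own group and 0.839 with the other T cell groups besides iFoxA1Treg. For nFoxA1Treg replicates 1 and 3 the own group was also slightly lower, and for the remaining arrays of EncT, nFoxA1Treg and Treg it was higher. Cd4, the coreceptor on which all groups were labelled, was 4.24 ± 0.10 in these arrays (log2, SD, n = 3), against 10.57 ± 0.017 in EncT, 10.44 ± 0.068 in nFoxA1Treg and 10.39 ± 0.057 in Treg. Cd274, which encodes PD-L1, was 10.01 ± 0.039, against 7.63 ± 0.16, 7.34 ± 0.13 and 7.31 ± 0.038 in the same order. The macrophage lysozyme gene Lyz2 was 12.36 ± 0.057 and the B cell receptor gene Cd79b 12.17 ± 0.048, while their means in the other groups were at most 5.18 and 3.79. Xist, transcribed from the inactive X chromosome of females, was 2.11 ± 0.85, against 11.07 ± 0.44 in EncT, 11.47 ± 0.27 in nFoxA1Treg and 11.52 ± 0.27 in Treg, whereas the Y-linked gene Eif2s3y was 9.66 ± 0.13 and at most 2.30 on average elsewhere. The low Cd4 level runs against the CD4hi label, so every direction given for the arrays labelled iFoxA1Treg is a direction for those arrays and not for a cell type. Low Xist with high Eif2s3y marks male RNA in those arrays, and the reverse marks female RNA in the other 9. Sex is therefore confounded with the label in every comparison of the arrays labelled iFoxA1Treg.

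**Figure D1:**
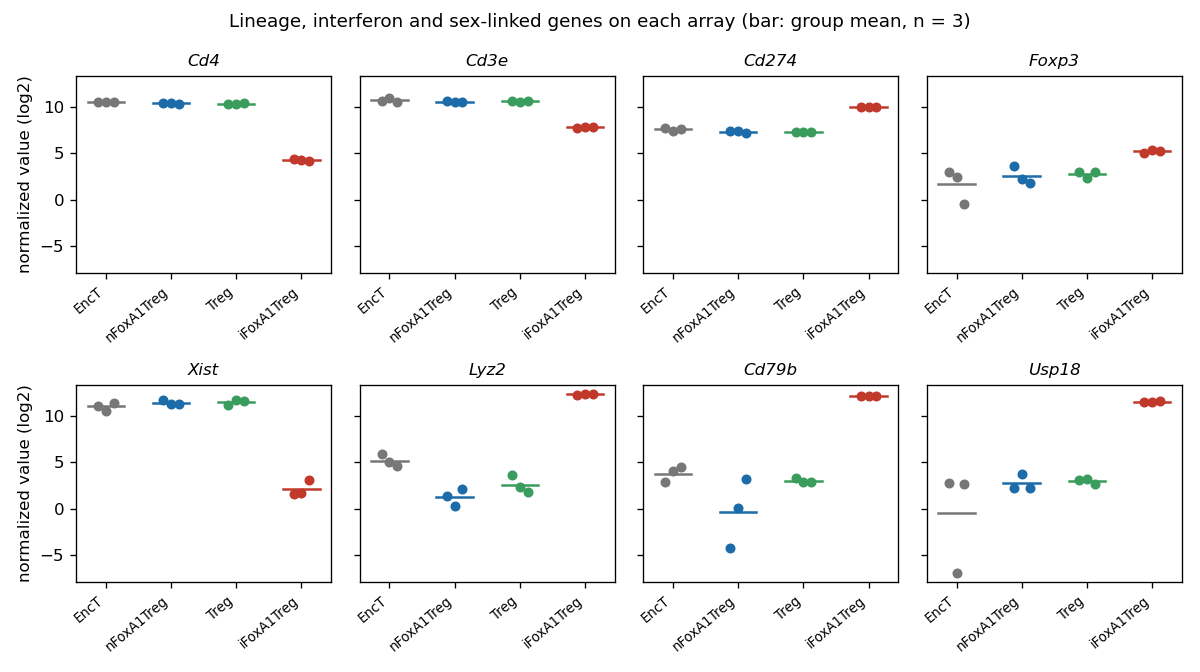
Normalized log2 values (vertical axis) of 8 genes on each of the 12 arrays, grouped by label along the horizontal axis, with points for arrays and bars for group means (n = 3). The arrays labelled iFoxA1Treg sit near 4.24 for Cd4 and 2.11 for Xist, below all other arrays, and near 12.36 for Lyz2 and 12.17 for Cd79b, above all other arrays.

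The comparison of nFoxA1Treg with EncT asks how FoxA1-named regulatory cells differ in transcripts from the disease-driving T cells. Asns, the asparagine synthetase gene, rose in nFoxA1Treg from 8.36 ± 0.22 to 9.58 ± 0.042 (SD, n = 3 each, 2.33-fold, adjusted p = 6.81e-06), and Slc7a5, a neutral amino acid transporter, was 2.90-fold higher (adjusted p = 8.20e-06). The inhibitory receptor gene Ctla4 rose 1.82-fold, from 9.95 ± 0.18 to 10.82 ± 0.077 (adjusted p = 1.61e-05). The lactate exporter gene Slc16a3 was 2.50-fold lower (6.61 ± 0.26 against 7.93 ± 0.47, adjusted p = 0.00115). The MHC class II gene H2-Aa fell as well, to 3.61 ± 0.49 against 5.69 ± 0.27 (adjusted p = 8.75e-05). On the log2(value + 16) scale, where the brightest probe set was chosen anew, H2-Aa changed by -1.74. Those levels and that change can therefore be of different probe sets.

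Of 12609 genes tested, limma called 2474 at an adjusted p under 0.05, 1067 higher and 1407 lower in nFoxA1Treg. At least a 2-fold change was seen in 20 of the higher and 100 of the lower genes. The values of the 3 arrays of each group did not overlap for 33.7% of the genes, where chance gives 10%. Among nonoverlapping called genes the largest rises were those of Fos, an immediate early transcription factor (3.63, SE 0.31, adjusted p = 1.55e-05), Apoe (1.60, SE 0.52), the insulin receptor substrate Irs2 (1.56, SE 0.12), Slc7a5 (1.53, SE 0.12) and the histone gene H2bc22 (1.41, SE 0.33). The largest falls were those of Cybb (-4.86, SE 1.31), Ccl6 (-4.27, SE 0.98), Lyz2 (-3.92, SE 0.48), the cytokine receptor chain Csf2rb (-3.86, SE 0.47) and the pattern receptor Clec7a (-3.65, SE 0.28), genes of myeloid cells. Several of these lie near the floor of the scale in 1 group, and on the log2(value + 16) scale the changes were 2.38 for Fos, 0.28 for Apoe with an adjusted p of 0.180, -1.35 for Cybb, -1.04 for Ccl6, -1.50 for Lyz2, -1.74 for Csf2rb and -2.18 for Clec7a. The filter took the mean over all 12 arrays, so genes dim in the other groups could pass through the arrays labelled iFoxA1Treg. Lyz2 did so, with means of 5.18 in EncT, 1.25 in nFoxA1Treg, 2.59 in Treg and 12.36 in those arrays (level 4.05). The count was 1524 without nFoxA1Treg replicate 1, 1517 without nFoxA1Treg replicate 2, 4721 with array weights and 1229 with only the arrays of the 2 groups.

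**Figure D2:**
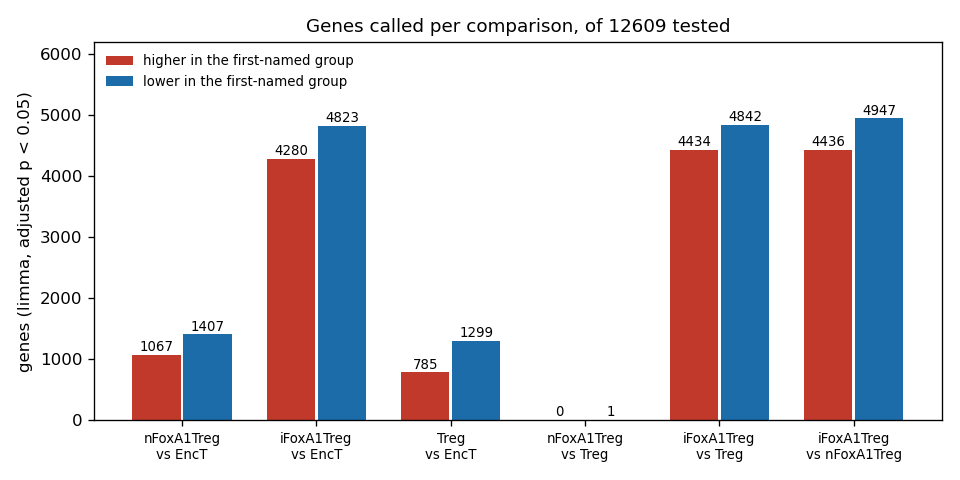
Number of genes called by limma (vertical axis, adjusted p under 0.05, of 12609 tested) in each of the 6 comparisons along the horizontal axis, with separate bars for genes higher and lower in the first-named group. The 3 comparisons with the arrays labelled iFoxA1Treg call 9103 to 9383 genes, and nFoxA1Treg against Treg calls 1.

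Of the 29 gene lists, camera called 12 in this comparison, 3 higher and 9 lower. Cell cycle genes stood higher: 24 of 41 rose, 1 fell and 16 did not pass the test, with 33 higher and 1 lower when adjusted over the list alone. The median was 0.32 (camera adjusted p = 1.98e-14, adjusted p = 0.235 with an estimated correlation). Rrm1, which makes deoxyribonucleotides, rose by 0.47, the replication clamp Pcna by 0.38 and the replication helicase subunit Mcm5 by 0.42, while the cyclin Ccne2 fell by 0.33. In the unfolded protein and integrated stress response list 16 of 27 rose, 1 fell and 10 did not pass the test, with 17 and 2 over the list alone. Its median was 0.28 (camera adjusted p = 6.93e-10, adjusted p = 0.0125 with an estimated correlation). Asns (1.22) and the mitochondrial serine hydroxymethyltransferase Shmt2 (0.88), among the 3 members with the smallest adjusted p, are enzymes of amino acid and one-carbon metabolism, Ppp1r15a (1.03) is a phosphatase subunit of the stress response, and the ubiquitin ligase Syvn1 fell by 0.23. Among mitochondrial respiratory chain genes 6 of 27 rose, 0 fell and 21 did not pass the test, with 7 and 0 over the list alone. The list median was 0.11 (camera adjusted p = 0.0119, adjusted p = 0.488 with an estimated correlation). Ndufa9 was at 0.18, Cox5b at 0.23 and Ndufv1 at 0.26.

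Glycolysis genes stood lower: 0 of 19 rose, 13 fell and 6 did not pass the test, with 0 higher and 18 lower over the list alone. The median change was -0.61 (camera adjusted p = 4.11e-08, adjusted p = 0.347 with an estimated correlation). Its leading members act around the pathway: Slc16a3 exports lactate, Pdk1 (-0.94) restrains the oxidation of pyruvate in mitochondria, and Egln3 (-0.73) is a prolyl hydroxylase of the oxygen-sensing system. Of Th1 effector genes 0 of 26 rose, 9 fell and 17 did not pass the test, with 0 and 10 over the list alone. The median lay at -0.14 (camera adjusted p = 0.00392, adjusted p = 0.0624 with an estimated correlation). The death ligand Fasl fell 2.002-fold, the chemokine receptor Cxcr6 1.25-fold, and the myeloid growth factor Csf2 by 1.26 on the log2(value + 16) scale. For the T cell receptor and T lineage list 0 of 27 rose, 5 fell and 22 did not pass the test, with 0 and 8 over the list alone. Their median was -0.14 (camera adjusted p = 0.00132, adjusted p = 0.0652 with an estimated correlation), with Bcl11b, a T lineage factor, at -0.40 and the receptor chain Cd247 at -0.24. Of quiescence and lymphoid homing genes 1 of 17 rose, 7 fell and 9 did not pass the test, with 1 and 9 over the list alone. The members had a median of -0.21 (camera adjusted p = 0.00237, adjusted p = 0.0624 with an estimated correlation). The interleukin 7 receptor Il7r fell 1.74-fold and Txnip, an inhibitor of glucose uptake, 1.46-fold, whereas the homing receptor Ccr7 rose by 0.38. Of migration and adhesion genes 0 of 22 rose, 8 fell and 14 did not pass the test, with 0 and 9 over the list alone. The median was -0.12 (camera adjusted p = 0.0117, adjusted p = 0.0774 with an estimated correlation), including Gpr183 at -0.73 and Gpr18 at -0.50.

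Interferon genes stood lower in nFoxA1Treg. In the type I interferon response 0 of 38 rose, 9 fell and 29 did not pass the test, with 0 and 11 over the list alone. Its median was -0.18 (camera adjusted p = 0.00275, adjusted p = 0.347 with an estimated correlation). The signalling factor Irf9 was at -0.65, Parp14 at -0.53 and Trim25 at -0.41. In the interferon gamma response 1 of 22 rose, 7 fell and 14 did not pass the test, with 1 and 9 over the list alone. The list median was -0.32 (camera adjusted p = 0.0145, adjusted p = 0.347 with an estimated correlation). The GTPase Irgm2 fell 2.41-fold, the signalling inhibitor Socs1 2.22-fold and the transcription factor Irf1 1.51-fold, while the chemokine Cxcl10 rose by 1.04. Markers of antigen-presenting cells were lower in the same arrays. Of the dendritic cell and MHC class II list 0 of 17 rose, 10 fell and 7 did not pass the test, with 0 and 10 over the list alone. The median change was -0.48 (camera adjusted p = 1.16e-04, adjusted p = 0.347 with an estimated correlation), and besides H2-Aa the invariant chain Cd74 fell by 2.17 and the chemokine Ccl22 by 2.93. Of the macrophage, microglia and monocyte list 0 of 17 rose, 6 fell and 11 did not pass the test, with 1 and 6 over the list alone. The median lay at -0.32 (camera adjusted p = 0.00853, adjusted p = 0.235 with an estimated correlation), a call that ended without the arrays labelled iFoxA1Treg in the fit (adjusted p = 0.223).

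The Foxp3 Treg core list was not called: 1 of 28 rose, 7 fell and 20 did not pass the test (1 and 7 over the list alone, median -0.15, adjusted p = 0.0846), with Ctla4 the member that rose and the Treg-associated factor Ikzf2, at -0.55, among those that fell. Of inhibitory receptors, ligands and suppressive mediators 1 rose and 7 fell of 24 (adjusted p = 0.280), and Cd274 was among the falls at -0.29 (SE 0.082, adjusted p = 0.0267). Immediate early genes split, with 8 higher and 9 lower of 29 (median -0.0049, mean 0.085, adjusted p = 0.889). The other lists without a call were Th17 effector (0 higher, 3 lower of 16, adjusted p = 0.278), Th2 effector (0 and 2 of 12, 0.671), apoptosis (4 and 6 of 29, 0.257), p53 targets (1 and 5 of 17, 0.257), TGF-beta response (0 and 2 of 22, 0.178), cholesterol synthesis (0 and 0 of 23, 0.257), heat shock (3 and 0 of 14, 0.257) and ribosomal proteins (0 and 2 of 20, 0.605). Marker lists of other cells without a call were B cell (0 and 3 of 16, adjusted p = 0.168), CD8 T and NK cell (0 and 3 of 15, 0.0646), neutrophil, mast cell and erythroid (0 and 1 of 10, 0.469), neuron (0 and 0 of 16, 0.605), astrocyte and oligodendrocyte (1 and 1 of 14, 0.961) and fibroblast and endothelial (0 and 0 of 14, median -0.064, mean 0.0090, 0.860).

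Foxa1 and Foxp3 lay below the level of 4.05 that probe sets had to reach, and are given from the fit without that filter. Foxa1 was 2.31 ± 0.27 in nFoxA1Treg and -5.54 ± 4.53 in EncT (SD, n = 3), with an adjusted p of 0.0199, a difference of 0.37 on the log2(value + 16) scale. Foxp3, the master factor of regulatory T cells, was 2.55 ± 0.95 and 1.66 ± 1.85 (adjusted p = 0.556). Differences that did not pass were -0.13 for Cd4 (adjusted p = 0.148), -0.039 for Cd47, 0.028 for Tgfb1, 0.093 for Pdcd1, 0.60 for Il10, -0.14 for Ifng, 0.046 for Il17a and -0.040 for Il2ra. In simulated data with the spread of these arrays, 58.7% of genes changed by 0.5 log2 were recovered, 90.8% at 1 and 98.3% at 2, with 4.31% of calls false. The simulations drew each gene independently, with 1 spread per gene for all groups and 200 of 12609 genes changed. These shares therefore need not hold for the real comparison, where genes move together and far more were called.

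Treg were compared with EncT as the reference for regulatory against disease-driving T cells. Ttr, which encodes the thyroxine carrier transthyretin, was 8.12 ± 0.35 in Treg and 2.51 ± 0.39 in EncT (SD, n = 3 each, adjusted p = 5.92e-07). Asns rose 2.12-fold (adjusted p = 2.41e-05) and Ctla4 1.58-fold (10.62 ± 0.035 against 9.95 ± 0.18, adjusted p = 2.15e-04). Slc16a3 was 2.84-fold lower (adjusted p = 7.06e-04) and Tnf, an inflammatory cytokine, 2.25-fold lower (adjusted p = 0.00130). Foxp3 was 2.77 ± 0.40 in Treg and 1.66 ± 1.85 in EncT in the fit without the filter, and did not pass (adjusted p = 0.444).

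Here limma called 2084 genes, 785 higher and 1299 lower in Treg, with 14 and 79 of them changed at least 2-fold. Nonoverlapping values were found for 33.3% of genes against 10% by chance. After Ttr (5.61, SE 0.28) the largest rises were in Fos (3.55, SE 0.31), Cxcl10 (2.64, SE 0.31), the tubulin gene Tubb2b (2.27, SE 0.41) and Apoe (2.02, SE 0.52). The largest falls were in Fcgr3 (-3.28, SE 0.51), Clec4n (-2.82, SE 0.56), Lyz2 (-2.59, SE 0.48), the beta globin gene Hbb-b2 (-2.41, SE 0.33) and Clec7a (-2.39, SE 0.28). On the log2(value + 16) scale the changes were 3.76 for Ttr, 2.31 for Fos, 1.67 for Cxcl10, 1.001 for Tubb2b and 0.45 for Apoe, and -0.99 for Fcgr3, -1.14 for Clec4n and -1.23 for Lyz2, whose levels lie near the floor in 1 group. Here too Lyz2 passed the filter only through the arrays labelled iFoxA1Treg. The split was 535 higher and 1417 lower with values as deposited and 429 higher and 1293 lower with arrays centred on their medians. The count was 1013 without Treg replicate 2, 1068 without Treg replicate 3, 4196 with array weights and 1140 with only the arrays of the 2 groups.

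Camera called 11 lists, 3 higher and 8 lower in Treg. Of cell cycle genes 24 of 41 rose, 0 fell and 17 did not pass the test, with 34 and 1 over the list alone. Their median was 0.29 (camera adjusted p = 2.93e-15, adjusted p = 0.222 with an estimated correlation), led by Mcm5 (0.41), Rrm1 (0.42) and Uhrf1 (0.44). In the unfolded protein and integrated stress response 11 of 27 rose, 2 fell and 14 did not pass the test, with 16 and 2 over the list alone. The members had a median of 0.17 (camera adjusted p = 4.07e-09, adjusted p = 0.0176 with an estimated correlation). Shmt2 was at 0.76 and Ppp1r15a at 0.86, while the chaperone Dnajb9 (-0.22) and Syvn1 (-0.20) were among the falls. Of respiratory chain genes 3 of 27 rose, 0 fell and 24 did not pass the test, with 2 and 0 over the list alone. The median was 0.066 (camera adjusted p = 0.0404, adjusted p = 0.635 with an estimated correlation), and that call ended without the arrays labelled iFoxA1Treg (adjusted p = 0.0505). Of glycolysis genes 0 of 19 rose, 15 fell and 4 did not pass the test, with 0 and 19 over the list alone. Its median was -0.60 (camera adjusted p = 3.87e-10, adjusted p = 0.289 with an estimated correlation). Pdk1 was at -1.08 and Egln3 at -0.70. Of Th1 effector genes 0 of 26 rose, 9 fell and 17 did not pass the test, with 0 and 9 over the list alone. The list median was -0.24 (camera adjusted p = 0.00344, adjusted p = 0.0717 with an estimated correlation). Fasl was at -0.85 and Cxcr6 at -0.34.

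For the T cell receptor and T lineage list 0 of 27 rose, 5 fell and 22 did not pass the test, with 0 and 8 over the list alone. The median change was -0.14 (camera adjusted p = 0.00536, adjusted p = 0.0944 with an estimated correlation). Gimap3 was at -0.49. Of quiescence and homing genes 1 of 17 rose, 6 fell and 10 did not pass the test, with 1 and 9 over the list alone. The median lay at -0.19 (camera adjusted p = 0.0144, adjusted p = 0.0944 with an estimated correlation). Txnip was at -0.55, Tob1, an inhibitor of proliferation, at -0.58 and Ccr7 again higher at 0.53. Of migration and adhesion genes 0 of 22 rose, 8 fell and 14 did not pass the test, with 0 and 8 over the list alone. Their median was -0.12 (camera adjusted p = 0.00936, adjusted p = 0.0944 with an estimated correlation), among them Ccr1 at -0.32, although its most variable probe set gave 0.014. In the type I interferon response 0 of 38 rose, 13 fell and 25 did not pass the test, with 0 and 17 over the list alone. The members had a median of -0.25 (camera adjusted p = 0.00137, adjusted p = 0.346 with an estimated correlation). Irf9 was at -0.61 and Parp14 at -0.53. In the interferon gamma response 1 of 22 rose, 7 fell and 14 did not pass the test, with 1 and 10 over the list alone. The median was -0.22 (camera adjusted p = 0.0173, adjusted p = 0.410 with an estimated correlation). Irgm2 was at -1.12, Irf1 at -0.62 and Cxcl10 the member that rose. Macrophage markers were lower in the same arrays: 0 of 17 rose, 5 fell and 12 did not pass the test, with 0 and 6 over the list alone. Its median was -0.21 (camera adjusted p = 0.0104, adjusted p = 0.222 with an estimated correlation), and the call ended without the arrays labelled iFoxA1Treg (adjusted p = 0.0943).

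Lists without a call included dendritic cell and MHC class II (0 higher, 3 lower of 17, adjusted p = 0.0737) and the Foxp3 Treg core (1 and 2 of 28, median -0.046, mean 0.011, adjusted p = 0.793). Cd274 fell by 0.33 (adjusted p = 0.0180). Cd4 differed by -0.18 (adjusted p = 0.0523), Il10 by 1.13 (adjusted p = 0.0810), Ifng by -0.22, Il17a by 0.073, Il2ra by -0.13, Pdcd1 by 0.16 and Cd47 by -0.078, none of them past the threshold. Tgfb1 showed no measurable difference (adjusted p = 0.9997). Foxa1, from the fit without the filter, was 1.97 ± 1.04 (adjusted p = 0.0292), and on the log2(value + 16) scale its difference of 0.33 did not pass (adjusted p = 0.0678). Changes against EncT were shared by the 2 groups: 670 genes were higher and 1028 lower in both nFoxA1Treg and Treg, with 0 opposite, where independent calls give 66.4 and 145. Both comparisons use the same 3 EncT arrays, which alone gave a correlation of 0.498 across genes in 100 simulations of unchanged groups, against 0.838 observed. The covariance was 0.0790, against 0.0138 in the simulations. The simulations drew each gene independently, so they do not cover a deviation of the 3 EncT arrays that many genes have in common.

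**Figure D3:**
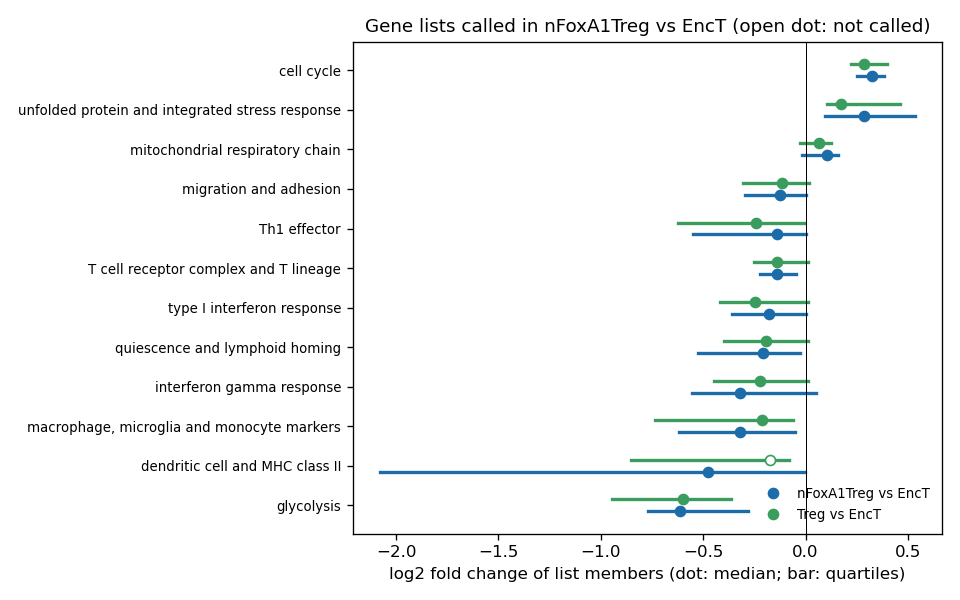
Log2 fold change of list members (horizontal axis, dots for medians and bars for quartiles) in the 12 gene lists called in nFoxA1Treg against EncT (vertical axis), with Treg against EncT beside them and an open dot where camera made no call. Glycolysis lies lowest, at medians of -0.61 and -0.60, and cell cycle highest, at 0.32 and 0.29.

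nFoxA1Treg were compared with Treg to ask what sets the FoxA1-named cells apart from other regulatory T cells. Ttr was lower in nFoxA1Treg, at 2.77 ± 0.44 against 8.12 ± 0.35 (SD, n = 3 each, adjusted p = 1.07e-06). It was the only gene called, and limma found 468 of 12609 genes at an unadjusted p under 0.05. Nonoverlapping values were found for 11.2% of genes against 10% by chance. The FoxA1 and PD-L1 transcripts that the group's name and label point to did not differ past the threshold: Foxa1, in the fit without the filter, was 2.31 ± 0.27 against 1.97 ± 1.04 (adjusted p = 0.9995), and Cd274 7.34 ± 0.13 against 7.31 ± 0.038 (adjusted p = 0.9997).

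The other fixed genes did not pass either, with differences of -0.22 for Foxp3, 0.052 for Cd4, 0.039 for Cd47, 0.028 for Tgfb1, -0.072 for Pdcd1, -0.53 for Il10, 0.084 for Ifng, -0.027 for Il17a, 0.090 for Il2ra and 0.20 for Ctla4. Camera called 6 lists, fry called 0, and no call held with an estimated correlation. Cholesterol synthesis genes stood higher in nFoxA1Treg (median 0.21 over 23 genes, camera adjusted p = 3.64e-10, adjusted p = 0.353 with an estimated correlation). Hsd17b7 was at 0.34, Fdft1 at 0.26 and Tmem97 at 0.24. The unfolded protein and integrated stress response list stood higher too (median 0.055, camera adjusted p = 0.00899, adjusted p = 0.256 with an estimated correlation). The dendritic cell and MHC class II list stood lower (median -0.37 over 17 genes, camera adjusted p = 5.87e-10, adjusted p = 0.256 with an estimated correlation). H2-Aa was at -1.18, Ccl22 at -2.08 and 5 members lower when adjusted over the list alone. Also lower were the Foxp3 Treg core (median -0.12, camera adjusted p = 0.00526, adjusted p = 0.590 with an estimated correlation), where the integrin Itgae was at -1.81 and Fgl2 at -0.30, quiescence and homing (median -0.028, camera adjusted p = 0.0286, adjusted p = 0.256 with an estimated correlation), where Il7r was at -0.40, and B cell markers (median -0.14, camera adjusted p = 0.0149, adjusted p = 0.256 with an estimated correlation). Without the arrays labelled iFoxA1Treg the B cell call ended (adjusted p = 0.687). The count of genes was 0 without Treg replicate 1, 2 or 3 and with the stricter filter, because the mean of every Ttr probe set then lay below the filter, so that Ttr was not tested. With every probe set fitted and no filter, the change in the Ttr probe set called was -5.35 (SE 0.30) with all arrays and -5.50 to -5.17 (SE 0.34 to 0.36) without 1 Treg array. The count was 2 without EncT replicate 1, 3 without EncT replicate 3 and without nFoxA1Treg replicate 2, 4 without nFoxA1Treg replicate 1 and 12 without nFoxA1Treg replicate 3. It was 10 with array weights, where H2-Aa, H2-Ab1, Cd74, Ccl22 and Il7r were called lower, and 4 with no filter.

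The arrays labelled iFoxA1Treg were compared with EncT to ask what distinguishes cells induced with interferon beta from disease-driving T cells. Interferon-induced genes were far higher in them: Ifit2 rose 17.3-fold (11.35 ± 0.041 against 7.24 ± 0.044, SD, n = 3 each, adjusted p = 4.88e-15), and Oasl1 went from 4.43 ± 0.37 to 12.29 ± 0.065. Cd274 rose 5.19-fold (adjusted p = 2.20e-11) and the regulatory cytokine gene Il10 by 3.05 (SE 0.41, adjusted p = 1.78e-05). Cd4 fell by 6.33 (SE 0.060, adjusted p = 3.52e-16), Ctla4 by 2.33, Pdcd1 by 3.71 and Tgfb1 by 3.87. Only the brighter Tgfb1 probe set fell, and the other past the filter differed by 0.066 (adjusted p = 0.670, every probe set past the filter tested). B cell and macrophage genes rose in the same arrays, including the B cell receptor partner Cd22 by 7.42 and the scavenger receptor Msr1 by 8.77.

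Of the genes tested, 9103 were called, 4280 higher and 4823 lower, with 1381 and 1819 changed at least 2-fold and 73.4% without overlap (10% by chance). With values as deposited the split was 3265 higher and 5768 lower, and the median of all genes shifted to -0.18 log2, against -0.024 after normalization. The largest rises were in the interferon-induced protease Usp18, the acute-phase gene Saa3, the chemokines Ccl12 and Ccl8, and the neutrophil granule gene Ngp. On the log2(value + 16) scale they were 7.23, 6.76, 8.90, 8.71 and 7.72, and on the normalized scale 12.07, 11.77, 10.60, 9.69 and 9.90. The largest falls were in Ermn, Msc, Mt3, Clgn and Xist, at -5.14, -5.03, -4.46, -3.49 and -6.71 on the log2(value + 16) scale and -14.73, -12.21, -9.62, -9.62 and -8.96 on the normalized scale. Foxp3 was 5.22 ± 0.18 against 1.66 ± 1.85 in the fit without the filter (adjusted p = 0.00133). Foxa1 was 0.82 ± 2.002 against -5.54 ± 4.53 (adjusted p = 0.0126), and did not pass on the log2(value + 16) scale (adjusted p = 0.126). Ifng fell by 2.63 and Il2ra by 2.80, Il17a differed by -0.23 (adjusted p = 0.654). Cd47 was at -0.16 (adjusted p = 0.0212) and turned to 0.60 (adjusted p = 0.00333) with its most variable probe set.

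Camera called 18 lists in the arrays labelled iFoxA1Treg against EncT, 10 higher and 8 lower, and 8 of the calls held with an estimated correlation. Markers of other leukocytes stood higher: of B cell markers 16 of 16 rose, 0 fell and 0 did not pass the test (median 6.38, camera adjusted p = 1.32e-09, adjusted p = 0.0102 with an estimated correlation), of macrophage markers 15 of 17 rose, 1 fell and 1 did not pass the test (median 3.37, camera adjusted p = 7.62e-07, adjusted p = 0.0197 with an estimated correlation). Adgre1 was at 6.99 and the microglial receptor Cx3cr1 lower at -1.69. Dendritic cell and MHC class II genes stood higher (13 rose and 2 fell of 17, median 1.62, camera adjusted p = 8.31e-04, adjusted p = 0.340 with an estimated correlation). H2-Aa was at 6.35 while the dendritic cell factor Batf3 fell by 4.18. Neutrophil, mast cell and erythroid markers (6 and 1 of 10, median 1.998, camera adjusted p = 0.0155, adjusted p = 0.113 with an estimated correlation) included Lcn2 at 7.02. Astrocyte and oligodendrocyte markers (10 and 2 of 14, median 0.66, camera adjusted p = 0.0263, adjusted p = 0.118 with an estimated correlation) were led by Clu (3.73) and Apoe (9.06), which macrophages also express, while the astrocyte filament Gfap fell by 1.45.

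Beside these markers, in the same arrays labelled iFoxA1Treg, the type I interferon response stood higher (36 of 38 rose, 1 fell and 1 did not pass the test, median 2.50, camera adjusted p = 1.82e-17, adjusted p = 0.0184 with an estimated correlation), as did the interferon gamma response (21 of 22 rose, 0 fell and 1 did not pass the test, median 1.42, camera adjusted p = 1.13e-08, adjusted p = 0.0362 with an estimated correlation). The restriction factor Bst2 was at 2.95 and Cxcl10 at 7.40. The unfolded protein and integrated stress response (21 rose, 3 fell of 27, median 0.78, camera adjusted p = 4.17e-06, adjusted p = 0.0184 with an estimated correlation) was led by Syvn1 (1.84) and the chaperone Pdia4 (2.66), while the serine synthesis enzyme Psat1 fell by 0.66. The other Pdia4 probe set past the filter was at 0.22 and was not called (adjusted p = 0.420, every probe set past the filter tested). Quiescence and homing genes (14 and 2 of 17, median 0.99, camera adjusted p = 1.97e-04, adjusted p = 0.0184 with an estimated correlation) included Klf2 at 6.67 and Ccr7 at 3.06, and Il7r was lower at -0.57. Immediate early genes stood higher (16 and 4 of 29, median 0.37, camera adjusted p = 0.00116, adjusted p = 0.1001 with an estimated correlation). Zfp36 was at 3.12. T cell receptor and T lineage genes stood lower (3 rose, 22 fell of 27, median -2.06, camera adjusted p = 5.76e-08, adjusted p = 0.0102 with an estimated correlation). Skap1 was at -2.66, Cd3g at -2.40 and the kinase Txk higher at 3.54. All 41 cell cycle genes fell (median -1.80, camera adjusted p = 2.50e-15, adjusted p = 0.118 with an estimated correlation), Ccnb2 by 2.71 and Birc5 by 2.45. Th1 effector genes stood lower (6 rose, 17 fell of 26, median -1.61, camera adjusted p = 0.00785, adjusted p = 0.0382 with an estimated correlation). Cxcr6 was at -3.73 and the Th1 factor Tbx21 at -2.26, while the chemokines Ccl3, Ccl4, Ccl5 and Xcl1 rose.

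Further lists stood lower in the arrays labelled iFoxA1Treg with calls that ended under an estimated correlation: Th17 effector (4 rose, 10 fell of 16, median -0.94, camera adjusted p = 0.0447, adjusted p = 0.141 with an estimated correlation), migration and adhesion (5 and 12 of 22, median -0.84, camera adjusted p = 0.0240, adjusted p = 0.0840 with an estimated correlation), glycolysis (1 and 13 of 19, median -0.59, camera adjusted p = 0.00826, adjusted p = 0.520 with an estimated correlation), cholesterol synthesis (2 and 16 of 23, median -0.60, camera adjusted p = 0.0190, adjusted p = 0.520 with an estimated correlation) and the respiratory chain (3 and 18 of 27, median -0.27, camera adjusted p = 0.0186, adjusted p = 0.498 with an estimated correlation). The fatty acid desaturase Scd1 rose by 4.77 within the cholesterol list, and Ndufa4 by 1.42 within the respiratory list. With values as deposited the Th17 (adjusted p = 0.0809) and migration calls (adjusted p = 0.0513) ended, and with arrays centred on their medians the respiratory chain call did (adjusted p = 0.171). The Foxp3 Treg core (10 rose, 16 fell of 28, median -1.25, adjusted p = 0.0556) and the inhibitory list (7 and 15 of 24, adjusted p = 0.0975) were not called. Where independent calls give 362 higher and 538 lower genes in both this comparison and nFoxA1Treg against EncT, 316 and 543 were found, and 1087 were opposite. Across genes the covariance of these changes was -0.0410, against 0.0141 from the shared EncT arrays alone in simulations of unchanged groups. The correlation was -0.0963. Its simulated value of 0.504 holds for groups in which no gene changes, so the 2 correlations are not on a like footing.

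Against Treg, the arrays labelled iFoxA1Treg again had high interferon and low T lineage levels, in a comparison that asks what separates these regulatory labels from each other. Irf7, an amplifier of the type I interferon response, rose by 5.07 (SE 0.097, n = 3 each, adjusted p = 6.78e-14), and Ifit2 by 4.11. Cd274 was 6.51-fold higher (10.01 ± 0.039 against 7.31 ± 0.038), and Il10 rose by 1.92 (adjusted p = 9.28e-04). Cd4 fell by 6.15, Tgfb1 by 3.87, Pdcd1 by 3.88, Ctla4 by 2.99, Il2ra by 2.67 and Ifng by 2.41. The second Tgfb1 probe set did not pass, at -0.17 (adjusted p = 0.251, every probe set past the filter tested). Foxp3, in the fit without the filter, was 5.22 ± 0.18 against 2.77 ± 0.40 (adjusted p = 0.0137). Foxa1 (-1.14, adjusted p = 0.641), Il17a (-0.30) and Cd47 (-0.086) did not pass. Cd47 did pass, and was higher, with its most variable probe set, at 0.88 (adjusted p = 1.84e-04), and with the mean of its probe sets, at 0.32 (adjusted p = 0.00197).

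In total 9276 genes were called, 4434 higher and 4842 lower, with 1521 and 1852 changed at least 2-fold and 77.7% without overlap (10% by chance). With values as deposited the split was 3541 higher and 5593 lower, and the median of all genes was -0.15 log2. Rises of 10.23 in Ccl12, 10.15 in Ccl6, 10.04 in the immunoglobulin segment Igkv6-14, 9.77 in Lyz2 and 9.59 in Ccl8 were the largest, and the largest falls were in Ermn (-14.73), Msc (-12.12), Mt3 (-9.82), Clgn (-9.73) and Xist (-9.41). These genes lie near the floor in 1 group, except Ccl8, so size and order on this scale depend on noise there. On the log2(value + 16) scale the rises were 8.78, 7.13, 7.62, 7.86 and 8.66, and the falls -5.14, -4.94, -4.65, -4.03 and -7.15, in the same order. Camera called 13 lists, 10 higher and 3 lower, of which 6 held with an estimated correlation. In the arrays labelled iFoxA1Treg, B cell markers (16 rose and 0 fell of 16, median 6.73, camera adjusted p = 3.16e-09, adjusted p = 0.0130 with an estimated correlation), macrophage markers (16 and 1 of 17, median 4.24, camera adjusted p = 3.48e-07, adjusted p = 0.0202 with an estimated correlation) and neutrophil, mast cell and erythroid markers (8 and 0 of 10, median 3.40, camera adjusted p = 0.00814, adjusted p = 0.09997 with an estimated correlation) stood higher. With them stood the dendritic cell and MHC class II list (12 and 1 of 17, median 1.80, camera adjusted p = 5.04e-04, adjusted p = 0.359 with an estimated correlation) and the astrocyte and oligodendrocyte list (9 and 2 of 14, median 0.66, camera adjusted p = 0.0459, adjusted p = 0.145 with an estimated correlation), where Batf3 (-4.59) fell in the former.

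Also higher in the arrays labelled iFoxA1Treg than in Treg were the type I interferon response (36 rose and 2 fell of 38, median 2.80, camera adjusted p = 6.65e-17, adjusted p = 0.0202 with an estimated correlation), the interferon gamma response (22 and 0 of 22, median 1.77, camera adjusted p = 4.55e-09, adjusted p = 0.0374 with an estimated correlation), quiescence and homing (15 and 1 of 17, median 0.98, camera adjusted p = 3.40e-05, adjusted p = 0.0130 with an estimated correlation), immediate early genes (21 and 5 of 29, median 1.08, camera adjusted p = 5.04e-04, adjusted p = 0.0956 with an estimated correlation) and the unfolded protein and integrated stress response (19 and 6 of 27, median 0.52, camera adjusted p = 0.00384, adjusted p = 0.0956 with an estimated correlation). Klf2 was at 7.27, Tob1 at 2.06 and the stress factor Ddit3 at 2.02. T cell receptor and T lineage genes stood lower (3 rose, 22 fell of 27, median -1.94, camera adjusted p = 5.16e-07, adjusted p = 0.0130 with an estimated correlation), as did the respiratory chain (2 and 20 of 27, median -0.26, camera adjusted p = 0.00570, adjusted p = 0.429 with an estimated correlation), and all 41 cell cycle genes fell (median -2.04, camera adjusted p = 1.63e-16, adjusted p = 0.121 with an estimated correlation). With arrays centred on their medians the respiratory chain call ended (adjusted p = 0.0548) and ribosomal proteins turned from a median of -0.055 to a call at 0.19 (adjusted p = 0.0264).

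The comparison of the 2 FoxA1Treg labels asks how the interferon beta and neuron routes differ. The arrays labelled iFoxA1Treg held more interferon-induced transcripts, with Irf7 at 4.97 (SE 0.097, n = 3 each, adjusted p = 8.57e-14) and the guanylate-binding protein Gbp2 at 2.62 (adjusted p = 3.21e-11). They held more Cd274 (6.34-fold, adjusted p = 6.73e-12) and Il10 (2.45, adjusted p = 1.22e-04), and less Cd4 (-6.20, adjusted p = 4.60e-16), Tgfb1 (-3.90), Pdcd1 (-3.81), Ctla4 (-3.19), Il2ra (-2.76) and Ifng (-2.49). For Tgfb1 this held for 1 of its 2 probe sets past the filter, the other being at -0.11 (adjusted p = 0.477, every probe set past the filter tested). Foxp3, in the fit without the filter, was 5.22 ± 0.18 against 2.55 ± 0.95 (adjusted p = 0.00850). Foxa1 did not differ past the threshold (0.82 ± 2.002 against 2.31 ± 0.27, adjusted p = 0.533), nor did Il17a (-0.28) and Cd47 (-0.12). For Cd47 the most variable probe set, at 0.89 (adjusted p = 1.72e-04), and the mean of its probe sets, at 0.32 (adjusted p = 0.00169), were higher and passed.

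Here 9383 genes were called, 4436 higher and 4947 lower, with 1565 and 1866 changed at least 2-fold and 77.7% without overlap (10% by chance). With values as deposited the split was 3520 higher and 5729 lower, and the median of all genes was -0.17 log2. The largest rises were in Cd79b (12.52), Ccl6 (11.38), Lyz2 (11.10), the phagocyte oxidase gene Cybb (11.08) and Ngp (10.37), and the largest falls in Ermn (-14.57), Msc (-12.18), Clgn (-9.78), Mt3 (-9.74) and Xist (-9.37). All 10 lie near the floor in 1 group, which leaves their size and order on this scale to noise there. In that order the changes on the log2(value + 16) scale were 7.93, 7.31, 8.14, 7.03 and 7.82, and -4.99, -5.00, -4.01, -4.58 and -7.11. Camera called 14 lists, 10 higher and 4 lower, of which 6 held with an estimated correlation. Higher in the arrays labelled iFoxA1Treg were markers of B cells (16 rose and 0 fell of 16, median 6.89, camera adjusted p = 1.73e-09, adjusted p = 0.0113 with an estimated correlation), macrophages (15 and 1 of 17, median 4.77, camera adjusted p = 3.88e-07, adjusted p = 0.0201 with an estimated correlation) and neutrophils, mast cells and erythroid cells (8 and 0 of 10, median 3.24, camera adjusted p = 0.00841, adjusted p = 0.110 with an estimated correlation). So were the dendritic cell and MHC class II list (14 and 1 of 17, median 2.23, camera adjusted p = 7.06e-05, adjusted p = 0.272 with an estimated correlation) and the astrocyte and oligodendrocyte list (9 and 2 of 14, median 0.60, camera adjusted p = 0.0338, adjusted p = 0.128 with an estimated correlation).

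With those markers, the arrays labelled iFoxA1Treg had higher levels in the type I interferon response (36 rose and 1 fell of 38, median 2.76, camera adjusted p = 4.71e-17, adjusted p = 0.0201 with an estimated correlation), the interferon gamma response (22 and 0 of 22, median 1.84, camera adjusted p = 4.71e-09, adjusted p = 0.0376 with an estimated correlation), quiescence and homing (16 and 1 of 17, median 0.96, camera adjusted p = 7.64e-06, adjusted p = 0.0113 with an estimated correlation), immediate early genes (21 and 5 of 29, median 1.12, camera adjusted p = 6.79e-04, adjusted p = 0.110 with an estimated correlation) and the unfolded protein and integrated stress response (18 and 7 of 27, median 0.47, camera adjusted p = 0.00921, adjusted p = 0.113 with an estimated correlation). Klf2 rose by 7.19, Egr3 by 2.55 and Pdia4 by 2.84, while Psat1 fell by 1.19. A second probe set past the filter was not called for Egr3, at 0.34 (adjusted p = 0.0643), or Pdia4, at 0.22 (adjusted p = 0.413, every probe set past the filter tested). Lower were T cell receptor and T lineage genes (4 rose, 22 fell of 27, median -1.84, camera adjusted p = 5.88e-07, adjusted p = 0.0113 with an estimated correlation), all 41 cell cycle genes (median -2.06, camera adjusted p = 2.62e-16, adjusted p = 0.124 with an estimated correlation), cholesterol synthesis (3 and 15 of 23, median -0.79, camera adjusted p = 0.0116, adjusted p = 0.545 with an estimated correlation) and the respiratory chain (2 and 21 of 27, median -0.27, camera adjusted p = 0.00492, adjusted p = 0.436 with an estimated correlation). Stard4 fell by 2.04, Lss by 1.35 and Sdhc by 1.54, whereas Scd1 rose by 5.09 and Ndufa4 by 1.67. The other Lss probe set past the filter, at -0.17, was not called (adjusted p = 0.403, every probe set past the filter tested). With arrays centred on their medians ribosomal proteins turned from a median of -0.038 to a call at 0.17 (adjusted p = 0.0454).

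Across the 4 groups, limma's F test called 9756 of 12609 genes. Genes that would set both FoxA1Treg labels apart had to be called in the same direction against both EncT and Treg in nFoxA1Treg and in the arrays labelled iFoxA1Treg. By limma there were 0 higher and 0 lower, where independent calls give 0 and 0.0164, since nFoxA1Treg against Treg called only Ttr (468 genes at an unadjusted p under 0.05). Leaving out that comparison, 194 genes were higher and 354 lower in the other 3. If calls shared by the 2 comparisons of the arrays labelled iFoxA1Treg were independent of those in nFoxA1Treg against EncT, the counts would be 324 and 485, more than were found. With array weights Ccl22 and Il7r, and without nFoxA1Treg replicate 3 Ccl22, Il7r and the isoprenoid enzyme Idi1, met all 4 conditions, with Ccl22 and Il7r lower and Idi1 higher in both labels.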

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

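The 5 tests of explanations for the arrays labelled iFoxA1Treg in the first pattern, the test of the macrophage list without them and the count of Ttr probe sets were chosen only after the result was seen. The effects of the 2 FoxA1Treg labels against EncT differed from each other, as tested by the contrast between them in the same fit. The arrays labelled iFoxA1Treg minus nFoxA1Treg gave list medians of -1.84 log2 for T cell receptor and T lineage (adjusted p = 5.88e-07, adjusted p = 0.0113 with an estimated correlation), 6.89 for B cell markers (1.73e-09 and 0.0113), 4.77 for macrophage, microglia and monocyte markers (3.88e-07 and 0.0201) and 2.76 for the type I interferon response (4.71e-17 and 0.0201). Single genes differed by -6.20 for Cd4 (adjusted p = 4.60e-16), 2.66 for Cd274 (6.73e-12) and -9.37 for Xist (2.52e-11), with all 3 arrays of each label on their own side.

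The first pattern is low T lineage and high B cell and myeloid levels in the 3 arrays labelled iFoxA1Treg. Normalization between arrays does not account for it, since in the deposited values the B cell list (median 6.31) and the T lineage list (-2.17) lay 8.48 log2 apart. Other cells mixed into CD4+ cells from like animals would lower Xist no more than the T lineage genes, but on the log2(value + 16) scale Xist changed by -6.71 (upper 95% bound -6.30), past the lower quartile of the T lineage changes at -2.76 (median -1.95). A change of state within CD4hi PD-L1hi cells is argued against by Cd4, at -6.33 and -8.48 against EncT in its 2 probe sets, and an exchange with another group of this series, all labelled CD4+ or CD4hi, by the highest of the 3 arrays lying at least 5.74 log2 below the lowest of the other 9 in both. RNA from a source outside the groups of this series, such as mixed leukocytes of a male animal, may account for the pattern. It cannot be told apart from the group, since the labels give no other source. In these arrays Xist was low, and 3 of 5 Y-linked genes were higher in all 3 than in all other 9. Such levels mark male RNA and also argue against a change of state in cells from like animals. Sex is thus confounded with the label.

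The second pattern is lower antigen-presenting and myeloid genes in nFoxA1Treg than in EncT. The shared normalization and filter with the arrays labelled iFoxA1Treg are argued against for the dendritic cell and MHC class II list, whose median was -0.46 without these arrays and -0.48 with them. For the macrophage list the median was -0.15 over 13 members without them and -0.32 over 17 with them, which left the joint explanation undecided there. Its 2 parts differ. The same 17 members give -0.32 without the arrays, which argues against the shared normalization for this list. The filter did act on it, as 4 members fell below the filter without those arrays. Fewer carried-over antigen-presenting cells may account for the pattern: of 126 genes at least 5 log2 higher in the arrays labelled iFoxA1Treg than in Treg, 90 (71.4%, exact 95% interval 62.7% to 79.1% that treats genes as independent, which they are not) were lower in nFoxA1Treg than in EncT, against 50.5% of the others, with 35 called lower and 2 higher. These genes were picked from the same data. They include genes of the pattern, such as Lyz2, and interferon-induced genes, such as Irf7 and Usp18. The share therefore cannot by itself single out carried-over antigen-presenting cells. In EncT the genes that such cells express abundantly were at 8.10 ± 0.16 for Cd74, 5.69 ± 0.27 for H2-Aa and 5.18 ± 0.66 for Lyz2 (SD), against 11.68 ± 0.056, 12.04 ± 0.024 and 12.36 ± 0.057 in the arrays labelled iFoxA1Treg. A sort gate that leaves out CD11b+ and CD11c+ cells would remove cells with those markers as a source, though not B cells. A difference in expression by the T cells themselves was not tested.

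The third pattern is Ttr high in the Treg arrays. A single cross-hybridising probe set is argued against, as 4 of 4 Ttr probe sets were higher in all 3 Treg arrays than in all other 9, although their changes against EncT ran from 0.61 to 10.99 log2 and 2 of them passed. The count cannot speak to cross-hybridisation that the 4 probe sets have in common, since they may share sequence. Choroid plexus tissue, which makes Ttr, could have been carried along, and cannot be told apart from expression in the Treg themselves: 0 of 21 other choroid plexus genes were higher in all 3 Treg arrays than in all 6 EncT and nFoxA1Treg arrays (1.19% by chance), and 8 were on average lower in Treg and the rest higher (exact sign test for lower, one-sided p = 0.905). Absence of the tissue predicts no difference in these genes rather than a fall, so the sign test could hardly decide. Those genes are less abundant than Ttr in that tissue, so a small share stays open, and no other biological explanation was tested.

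Splitting the 6 arrays of a comparison into 2 groups of 3 gives 10 splits, too few for a share under 0.05. The real splits called 2474 genes and 12 lists for nFoxA1Treg against EncT (at most 2 and 11 in another split), 2084 genes and 11 lists for Treg against EncT (at most 0 and 11 in another split), 1 gene and 6 lists for nFoxA1Treg against Treg (at most 1 and 6 in another split), 9103 genes and 18 lists for the arrays labelled iFoxA1Treg against EncT (at most 0 and 13 in another split), 9276 genes and 13 lists for the same arrays against Treg (at most 0 and 13 in another split) and 9383 genes and 14 lists for the same arrays against nFoxA1Treg (at most 0 and 12 in another split). For nFoxA1Treg against Treg 3 of the 10 splits called as many genes and 3 as many lists, and 2 of the 10 did so for the lists of Treg against EncT and of the arrays labelled iFoxA1Treg against Treg. Among 100 splits of the 12 arrays into 4 groups, 1, the real one, called as many as 9756 genes by the F test. The highest other called 8616. A share of 1 in 100, the smallest these splits can give, argues against a random grouping of these samples. The high count in another split leaves open which groups differ.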

How the results depend on the processing

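The fits on the log2(value + 16) scale and without the arrays labelled iFoxA1Treg were chosen only after the results were seen, and the other alternatives were planned. Signal over background limits genes near the floor of the scale, Foxa1 and Foxp3 among them. Of 326 values of named genes, 272 were called, and of 8157 values under alternatives 8008 kept their side of the threshold without a called value reversing (among them 50 uncalled values that changed sign), 110 lost and 31 gained a call, and 8 reversed. The pseudocounts planned for linear values were not run because the values are log2. Where values moved, the cause was not tested.

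Against 1 gene called in nFoxA1Treg against Treg there were 4 with no filter, 0 with the upper 40%, 2 with the mean of all probe sets, 2 with the most variable probe set, 2 with every probe set tested and 3 on the log2(value + 16) scale. Array weights gave 4721 genes for nFoxA1Treg against EncT, 4196 for Treg against EncT, 10 for nFoxA1Treg against Treg and 2 genes setting both FoxA1Treg labels apart (0 in the fit reported). Only the arrays of the 2 groups gave 1229 and 1140 genes against EncT for nFoxA1Treg and Treg. The most variable probe set gave 7 lists for Treg against EncT, and arrays centred on their medians 10 for nFoxA1Treg against Treg. Camera with an estimated correlation called 1 list for nFoxA1Treg and 1 for Treg against EncT, 0 for nFoxA1Treg against Treg, and 8, 6 and 6 for the arrays labelled iFoxA1Treg against EncT, Treg and nFoxA1Treg. Fry called 28, 29 and 29 for those and 0 for nFoxA1Treg against Treg.

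Reversals were those of Cd47 in the arrays labelled iFoxA1Treg and of Ccr1. Against EncT, Cd47 was 0.0021 with arrays centred on their medians, 0.14 with the mean of probe sets and 0.60 with the most variable. Against Treg it was 0.32 and 0.88, and against nFoxA1Treg 0.32 and 0.89, with those probe sets. Ccr1 in Treg against EncT was 0.014 with the most variable probe set.

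Leaving out each of the 12 arrays in turn gave 1517 to 3010 genes for nFoxA1Treg against EncT (lowest without nFoxA1Treg replicate 2, highest without EncT replicate 2), 1013 to 2716 for Treg against EncT (without Treg replicate 2 and EncT replicate 2) and 0 to 12 for nFoxA1Treg against Treg (lowest without any 1 Treg array, where Ttr lay below the filter, highest without nFoxA1Treg replicate 3). For the arrays labelled iFoxA1Treg it gave 8635 to 9135 against EncT, 8727 to 9453 against Treg and 8825 to 9511 against nFoxA1Treg, for the F test 9159 to 9860, and for genes setting both labels apart 0 to 3 (3 without nFoxA1Treg replicate 3). Lists called ran from 12 to 17, 9 to 13 and 4 to 7 for the comparisons in the order above, and 17 to 19, 12 to 15 and 13 to 16 for the arrays labelled iFoxA1Treg.

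The replicate numbers share no stated origin. Over the 18 pairs of same-numbered arrays, correlations of deviations from group means ran from -0.163 to 0.166, with 2 above 0.1. With the number as a replicate block, nFoxA1Treg against Treg gave 2 genes, nFoxA1Treg against EncT 2343 and Treg against EncT 1880. Without the arrays labelled iFoxA1Treg, 2270 genes were called for nFoxA1Treg against EncT and 1782 for Treg against EncT, of which 2113 and 1630 were called with all arrays in the same direction, and Ttr stayed the 1 gene of nFoxA1Treg against Treg.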

Other observations

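The genes in this part were chosen only after their values were seen, and no test of an explanation was made. Immediate early genes moved apart within their list in both nFoxA1Treg and Treg against EncT. In nFoxA1Treg the rises included the AP-1 factor Fos (3.63), the NF-kappaB inhibitor Tnfaip3 (1.23), the phosphatase Dusp1 (1.16) and the activation marker Cd69 (0.89), and the falls included Ier3 (-1.96), the antiproliferative Btg2 (-1.46) and Dusp2 (-0.92). Treg showed the same directions for Fos (3.55), Tnfaip3 (0.92), Dusp1 (0.99), Cd69 (0.94), Ier3 (-1.78) and Btg2 (-1.33). All of those given passed the test in their comparison.

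Single genes of cytokine reception, chemotaxis, cell death and low-oxygen metabolism moved the same way in both groups. The interleukin 18 receptor chains Il18r1 and Il18rap were at -1.28 and -0.86 in nFoxA1Treg and at -0.90 and -0.92 in Treg, and the chemokine Ccl5 at -0.90 and -1.04. Among p53 targets the proapoptotic Bbc3 was at -0.93 and -0.85 and Sesn1 at -0.70 and -0.78, while the nuclease Aen rose by 0.56 and 0.48. The glycolytic aldolase Aldoc was at -2.02 and -2.07, and Bnip3, a mitophagy receptor induced by low oxygen, at -1.31 and -1.47. All of these passed the test against EncT. None was called in nFoxA1Treg against Treg, which does not show that the 2 effects are equal.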
